A study of Homo sapiens with 9 samples.

How the data were processed

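RNA was sequenced from E14 cells, a male mouse embryonic stem cell line, in 3 groups of 3 libraries. The groups were the parental cells, cells with a low exogenous level of Zmynd8 and cells with a high exogenous level of Zmynd8. Per the labels' protocols, cells were kept in medium with 15% serum and 1000 U/ml LIF, doxycycline was added at 5 µg/ml 24 h after plating to switch on exogenous Zmynd8, and RNA was taken 24 h later. The treatment text was identical on the labels of all 9 libraries, parental ones included, so whether the parental cells received doxycycline was left open. Libraries were made with a NEBNext Ultra RNA kit from 2 µg of total RNA. The organism field of the labels names another species, but the cell type, the genome build and the gene identifiers were those of mouse.

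The deposited table held raw counts per gene for all 9 libraries, with no normalization. Per the file headers, fragments were counted over gene_id with featureCounts 1.6.2 on the Ensembl release 92 annotation of GRCm38, without regard to strand. Per the submitters' processing notes, STAR 2.5.3a and deepTools 3.1.3 were also used, and the build was GRCm38 (mm10). Because strand was not used, reads of a gene and of an antisense or overlapping gene cannot be told apart. Counts of near-identical gene copies are uncertain, since their shared reads cannot be assigned. The folder name in the header pointed to alignments from which duplicate reads had not been removed.

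The table had 53801 genes, and 31537 of them had a count in some library. Totals per library were between 21051708 and 26441429 counts, and CPM here are counts scaled to the TMM-adjusted total of each library. Replicates of each group were compared by a chi-square statistic over genes with at least 50 counts in each pair. It was between 2.86 and 9.01 per degree of freedom, so every pair differed by more than sampling noise and all 9 libraries were kept as separate samples. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Each overexpressing group may also be a single derived line, in which case the Zmynd8 level and the line cannot be separated.

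The files do not pair gene identifiers with symbols. The reference tables given with the files were human, and 0 of the mouse identifiers matched them. The 26 gene lists fixed before the data were examined, with 513 gene names, were therefore not tested, and at most 2 identifiers that rose and 2 that fell are printed. The Zmynd8 row was located by exon structure. The ordered lengths of the 21 internal coding exons of human ZMYND8, from the human annotation given with the files, were matched to the exons of each gene in the table. ENSMUSG00000039671 matched 18 of the 21 lengths in order, and the next best gene of the table matched 6. Matched back against human genes, its best partner was ZMYND8 with 18, and the next best human gene reached 10. That row is called Zmynd8 here, and it counts endogenous and exogenous transcripts together as far as the latter carry the annotated exons.

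Genes were tested with edgeR 4.0.16 in R 4.3.3, using the quasi-likelihood F test with robust estimation, TMM scaling and filterByExpr by group. All 9 libraries entered 1 fit with group as the only term. Adjusted p is the Benjamini-Hochberg value over the 17171 genes kept, and genes with an adjusted p under 0.05 are said to have risen or fallen. A second count took those with an absolute log2 fold change of at least 1. Standard errors were derived from the fitted fold change and its F value. The common biological coefficient of variation was 5.13%.

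The fit was tested on simulated counts for the 17171 genes, with 50 genes changed at each of 4 sizes per comparison. The changed genes were drawn from those with at least 90 counts in all. With only 200 genes changed, an adjusted p under 0.05 is harder to reach than in the data. The shares below are therefore not the sensitivity of the real calls. For low against parental it recovered 94% of 4-fold, 80% of 2-fold, 52% of 1.5-fold and 48% of 1.2-fold changes, with 10 false calls. For high against parental the shares were 94%, 72%, 64% and 46%, with 10 false calls. For high against low they were 92%, 82%, 64% and 24%, with 7 false calls.

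Before the data were examined, the named genes were fixed as Zmynd8 and, for each overexpressing group against parental, the 10 genes that rose and the 10 that fell by the largest log2 fold change. They had to have an adjusted p under 0.05, a mean of at least 2 CPM over both groups, and no overlap between the groups' libraries. For high against low 5 and 5 were taken. Genes of the Y and mitochondrial chromosomes were passed over. The part of the rule that passed over predicted gene models needs symbols and was not applied.

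For each chromosome, the median log2 fold change of its tested genes was taken relative to that of all genes. It was tested by 100000 permutations of the chromosome labels over genes, adjusted over 22 chromosomes (two-sided). Genes are not independent replicates, so these tests compare chromosomes within the fitted values. Shares of counts per library were compared by exact permutation of the libraries (two-sided). Parental libraries were set against the 6 others, and high libraries against the 6 others, without adjustment for testing both. After the data had been seen, windows of 5 Mb with at least 10 tested genes, windows of 3 Mb with 10000 permutations, adjacent gene pairs with 10000 shuffles, and gene length were added. Overlap of calls against the shared parental libraries was set beside 20 simulations of unchanged groups. After the data had been seen, 20 simulations with unchanged low cells and 20 with the low changes moved to other genes within 20 bins of expression were added. In both, high cells had the fitted changes of the genes called, and genes not called were left unchanged. The split of simulated genes by depth was also added then. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for these steps, and matplotlib 3.10.9 for plots.

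Alternatives fixed before the data were examined were RLE and upper-quartile scaling, the DESeq2 1.42.0 Wald test, no low-count filter (at least 1 count in all), and a stricter filter of 1 CPM in at least 3 libraries and 50 counts in all. The others were fits of only the groups compared, a replicate block, each library left out in turn, genes of chromosomes shifted by over 0.1 left out, and an adjusted p under 0.01. Counts without the genes of chromosome 11 were added after the data had been seen. GC content was not examined, since no mouse genome was used here.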

Results

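The transcriptomes of parental E14 embryonic stem cells and of derived cells with a low or a high exogenous level of Zmynd8 were compared by RNA sequencing, with 3 libraries per group. Zmynd8 is a nuclear protein that binds modified histone tails. Library totals were between 21051708 and 26441429 counts, and 17171 genes were tested. In a principal component analysis of the 9 libraries, the first component held 49.0% of the variance and set the high group apart from both others. The second component held 13.1% and set low apart from parental.

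Zmynd8 was higher in both derived groups, in the order of their labels. The row taken as Zmynd8 (ENSMUSG00000039671, GRCm38 chromosome 2, 165784152 to 165899016, minus strand) had 230 ± 1.39 CPM (counts scaled to library size) in parental cells (SD, n = 3). It had 316 ± 5.05 in low and 577 ± 31.5 in high cells (SD, n = 3 each). The counts were 5881, 5212 and 4867 in parental, 7630, 7244 and 7984 in low, and 14852, 12432 and 12542 in high libraries. The log2 fold change was 0.46 ± 0.041 (SE) for low against parental (edgeR adjusted p = 1.0e-12) and 1.33 ± 0.042 for high against parental (adjusted p = 3.0e-32). High lay above low by 0.87 ± 0.041 on the log2 scale (edgeR adjusted p = 1.2e-24). These values correspond to 1.37-fold, 2.51-fold and 1.83-fold.

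**Figure D1:**
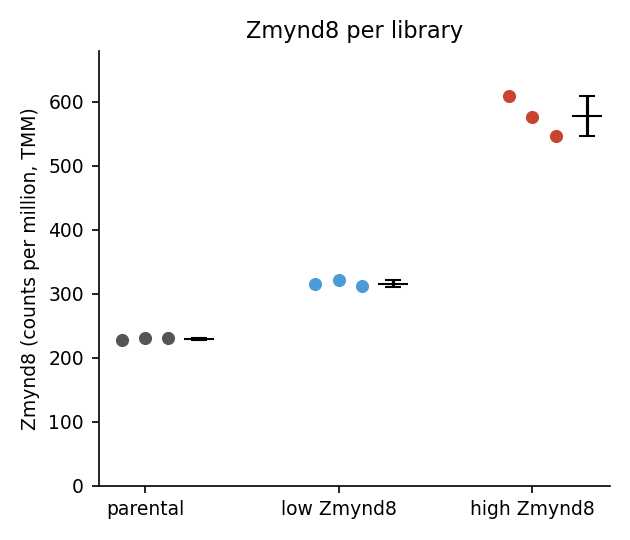
Zmynd8 in CPM (TMM scaled, vertical axis from 0) in each library of the 3 groups (horizontal axis). Points are libraries and the bars to their right are mean ± SD, n = 3. The group means were 230, 316 and 577, and the groups did not overlap.

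Low cells were compared with parental cells. This contrast also holds any other difference of the derived cells, and that of doxycycline if the parental cells received none. Genes of chromosome 11 were lower as a group: 650 of its 1383 tested genes fell and 21 rose. They made up 37.6% of all genes that fell. Away from chromosome 11, 1386 genes rose and 1077 fell. The largest fall by the naming rule was that of ENSMUSG00000028270 (chromosome 3, 142620602 to 142638008), from 3.74 ± 0.866 to 0.385 ± 0.039 CPM (SD, n = 3 each; log2 fold change −3.25 ± 0.254 SE, edgeR adjusted p = 1.0e-14).

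In all, 3134 of the 17171 genes changed in low cells, 1407 up and 1727 down (edgeR, adjusted p under 0.05). Most changes were small, with a median of 0.31 on the log2 scale in size, and 198 genes changed by 2-fold or more (58 up, 140 down). The groups did not overlap for 2960 of the 3134 genes, and for 5295 (30.8%) of all genes tested, where chance gives 10%. The 10 named risers reached log2 fold changes of 0.95 to 1.44 and lay on 9 chromosomes. The 10 named fallers had −3.25 to −1.66, 3 of them on the X chromosome and 2 on chromosome 11. With chromosomes 11 and Y left out of the fit, 993 genes fell. With the DESeq2 test, 111 genes changed by 2-fold or more, and at an adjusted p under 0.01 edgeR called 1951.

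High cells were compared with parental cells in the same way and with the same limit. More genes changed and by more: 3920 rose and 3788 fell, 7708 in all (44.9% of those tested; edgeR, adjusted p under 0.05). Of these, 925 rose and 477 fell by 2-fold or more. Chromosome 11 genes were again lower, with 730 fallers and 104 risers, while genes of the X chromosome were higher, with 213 risers and 78 fallers among 572. The median change of called genes was 0.42 on the log2 scale in size. The groups did not overlap for 7179 of the called genes, and for 50.8% of all genes tested against 10% by chance.

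ENSMUSG00000022044 (chromosome 14, 66344296 to 66361680) rose most in high cells by the naming rule and was near absent elsewhere. It had 411 counts over the 3 high libraries (5.94 ± 0.995 CPM, SD, n = 3), 2 over the parental and 0 over the low libraries. Scaled for depth, the ratio of high to parental was 207 (95% exact Clopper-Pearson interval 57.0 to 1717, counting error only; edgeR adjusted p = 1.3e-18). The ratio was 130 without parental replicate 1 and 140 without parental replicate 2. Both parental counts were in replicate 3, and without it the ratio was at least 96.2, taking 3 counts over the 2 other libraries as the limit. The fitted log2 fold change was 7.44, and 10.14 without that library, which is no measured size. Against low cells it was at least 144-fold higher, taking 3 counts over the low group as the limit that a count of 0 allows. The remaining 9 named risers had log2 fold changes of at least 3.90. In low against parental, which shares the parental libraries, 1 of the 10 named risers rose and 4 fell.

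ENSMUSG00000034911 (chromosome 8, 71384272 to 71395802) fell most in high cells by the naming rule, from 12.3 ± 1.39 to 1.79 ± 0.401 CPM (SD, n = 3 each; log2 fold change −2.78 ± 0.174 SE, edgeR adjusted p = 1.6e-19). It was intermediate in low cells at 3.91 ± 0.635 and also fell there. The 10 named fallers had log2 fold changes of −2.78 to −1.92, and 4 of them lay on chromosome 11. In low against parental 8 of these 10 fell as well, a comparison that shares the parental libraries used to choose them.

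High cells were set against low cells to ask what differed between the labelled levels. Here 3027 genes rose and 2919 fell, 5946 in all, 799 and 268 of them by 2-fold or more (edgeR, adjusted p under 0.05). X-linked genes were higher in high cells, with 183 risers and 46 fallers. Chromosome 11 genes went both ways, with 221 risers and 290 fallers. The 5 named risers had log2 fold changes of at least 5.62, and the 5 named fallers had −2.26 to −1.60. ENSMUSG00000028270, which fell in low cells, rose in high cells to 17.7 ± 0.466 CPM (SD, n = 3; log2 fold change against parental 2.25, edgeR adjusted p = 3.2e-19).

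Genes called in both derived groups, at any size of change, mostly went the same way. Together 858 rose in both and 1239 fell in both, 2097 in all. Independent lists of these sizes would share 321 and 381. Of the 2097, 526 lay on chromosome 11, and without that chromosome 852 rose and 719 fell in both, against 335 and 209 for independent lists. A further 114 rose in low and fell in high, and 137 fell in low and rose in high, where independent lists would share 310 and 394. Large changes included opposite ones. In 34 genes both changes were 2-fold or more, and each of them fell in low and rose in high cells. In low cells 140 genes fell by 2-fold or more in all. Genes with changes of that size in the same direction were not counted.

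Both comparisons use the same parental libraries, which alone makes their fold changes alike. In 20 simulations of unchanged groups against those libraries, at most 1 gene was called in the same direction in both (mean 0.15), but with 0 to 4 genes called per comparison they give no reference for the overlap of changed genes. In 20 further simulations the fitted changes of high cells were kept and those of low cells were moved to other genes of like expression. There 277 ± 15.2 genes rose in both and 476 ± 19.3 fell in both, while 267 ± 14.4 rose in low and fell in high and 256 ± 16.5 did the reverse (SD, n = 20 simulations). These lists were shorter than the real ones, with means of 2597 genes called in low and 6895 in high against 3134 and 7708, so the counts are not a matched reference. Across the 16388 genes with at least 90 counts, which are not independent replicates, the fold changes had a correlation of 0.316 and a covariance of 0.0680. Without chromosome 11 these were 0.282 and 0.0588. In the 20 simulations of unchanged groups the correlation was 0.496 ± 0.013 and the covariance 0.0224 ± 0.00095 (SD). The covariance over all chromosomes differed by 0.0456. Those simulations held no changes, so their correlation is no matched reference. Neither value was computed with the low changes moved. The 3 parental libraries cannot be split into parts of at least 2, so part of the excess in shared calls may come from the shared controls.

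**Figure D2:**
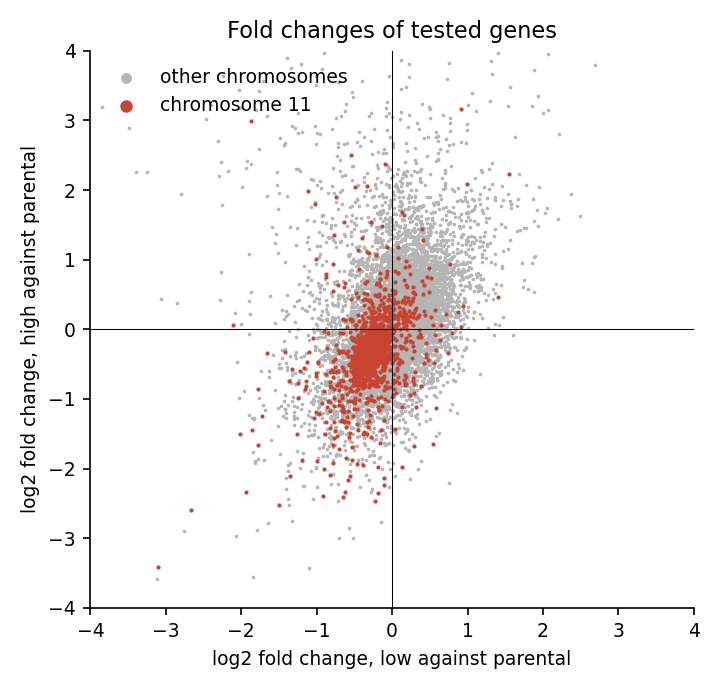
Log2 fold change of each tested gene in low against parental (horizontal) and high against parental (vertical), with genes of chromosome 11 in red and all others in grey. Of the 17171 genes, 17136 are drawn and 35 lie outside the axes. Chromosome 11 genes sit mostly in the lower left, where both changes are negative.

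Of the 7708 genes called in high against parental, 5388 (69.9%) had a low-cell value between the parental and the high one. In 20 simulations with unchanged low cells and the fitted changes of high cells this share was 54.0% ± 0.658, and with the changes of low cells moved to other genes it was 49.8% ± 0.592 (SD, n = 20 each). Of the 7708, 5360 were not called in low against parental. High cells went beyond low cells in the same direction, past the test of high against low, for 4574 (59.3%) of them. This share was 91.6% ± 0.271 with unchanged low cells and 84.9% ± 0.434 with the low changes moved (SD, n = 20 each), so it is no evidence of a graded response. Called in all 3 comparisons in this order were 703 genes. For 85 genes high cells fell back relative to low cells past the test, and 1740 (22.6%) had the opposite sign in low cells, against 45.8% ± 0.660 and 45.3% ± 0.495 in the simulations (SD, n = 20 each). The median ratio of the low to the high log2 fold change was 0.322, against 0.0192 ± 0.00288 and 0.0289 ± 0.00283 in these simulations (SD, n = 20 each), and it was 0.661 on chromosome 11.

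Several chromosomes departed from the rest, and among autosomes chromosome 11 did so most in both comparisons with parental cells. The median log2 fold change of chromosome 11, relative to that of all genes, was −0.28 in low and −0.29 in high against parental (permutation adjusted p = 0.00011 in each; the unadjusted p of 1.0e-05 is the smallest that 100000 permutations can give). It was −0.01 in high against low (adjusted p = 0.184). Chromosome 11 took 11.9% ± 0.0372 of all counts in parental libraries, 9.93% ± 0.0026 in low and 9.97% ± 0.0131 in high libraries (SD, n = 3 each). Parental libraries differed from the 6 others with an exact permutation p of 0.0119, the smallest that 84 splits can give. Smaller departures were called as well: 0.03 to 0.04 for chromosomes 3, 9, 12 and 13 in low against parental, 0.04 to 0.08 for chromosomes 1, 3, 8, 12, 14 and 18 in high against parental, and −0.03 to 0.04 for chromosomes 1, 4, 7, 14 and 18 in high against low (permutation, adjusted p under 0.05). The median of all genes includes the chromosome 11 genes, which lowers it slightly in both comparisons with parental cells. Part of the positive departures there may come from this. The smaller departures were not corrected for expression level or gene length.

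The X chromosome median was 0.17 in high against parental (permutation adjusted p = 0.00011) and 0.15 in high against low (adjusted p = 0.00022), but −0.0023 in low against parental (adjusted p = 0.901; 0.0055 without parental replicate 3). X-linked genes took 2.84% ± 0.016 of counts in high libraries, 2.70% ± 0.0156 in low and 2.67% ± 0.0249 in parental libraries (SD, n = 3 each). High libraries were above all 6 others (exact permutation p = 0.0119, the smallest possible).

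Mitochondrially encoded genes had a median of 0.31 in high against parental (permutation adjusted p = 0.00277), with 11 risers and 2 fallers among 28, but they did not move together. Of the 13 longer than 250 bases, 6 rose and 2 fell. These were picked by length alone, without regard to the type of RNA, so they are not a set of mRNAs. The one with the highest CPM, at 5328 to 6872, fell from 8964 ± 184 to 8106 ± 233 CPM (SD, n = 3 each). Its log2 fold change was −0.15 (edgeR adjusted p = 0.00225). The longer genes at 7013 to 7696, 7927 to 8607, 8607 to 9390 and 9459 to 9806 had only 0.763 to 2.02 CPM in parental cells. Several shorter genes were also near the floor, down to 0.194 CPM, so the median rests partly on few counts. Why these counts were low was not tested. All mitochondrially encoded genes took 1.68% ± 0.0543 of counts in high, 1.52% ± 0.0908 in low and 1.40% ± 0.0479 in parental libraries (SD, n = 3 each). Against low cells the median was 0.26 (adjusted p = 0.0066). Without parental replicate 1 the median of high against parental was 0.03 and passed no threshold (adjusted p = 0.826). With no low-count filter the medians were 0.19 and 0.17, again without a call. The 9 tested Y-linked genes had a median of −0.51 in low against parental (adjusted p = 0.00114), with 2 risers and 4 fallers, and −0.33 with no low-count filter (29 genes). The share of counts of all Y-linked genes was not lower there, at 0.0510% ± 0.00317 in low and 0.0487% ± 0.00025 in parental libraries (SD, n = 3 each; not tested). The median was −0.12 in high against parental (adjusted p = 0.593), which was 0.03 without parental replicate 1 or without high replicate 2.

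**Figure D3:**
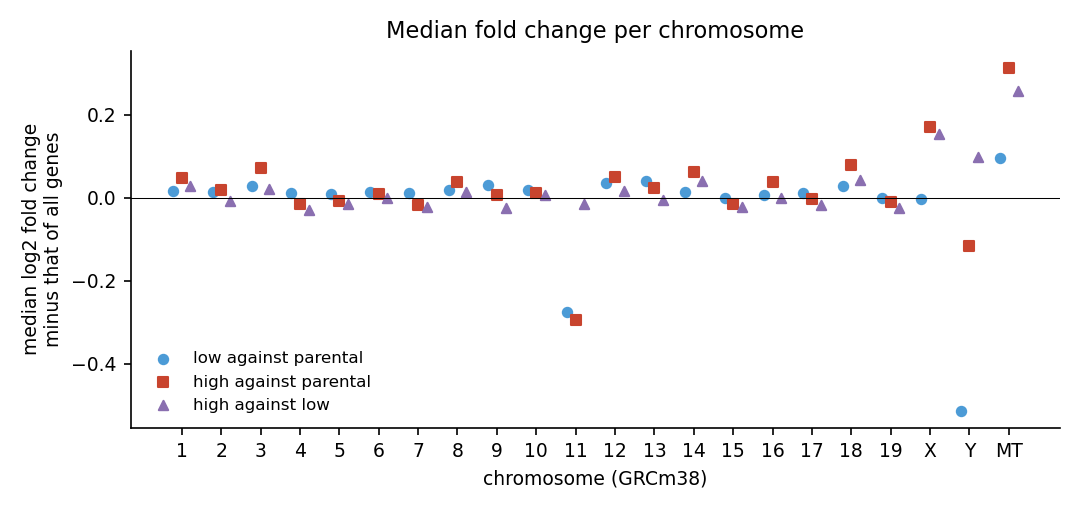
Median log2 fold change of the tested genes of each chromosome minus that of all genes (vertical), by chromosome (horizontal), for the 3 comparisons. Chromosome 11 lies at −0.28 and −0.29 against parental and at −0.01 in high against low. X lies at 0.17 and 0.15 in the comparisons with the high group, and Y rests on 9 genes and MT on 28.

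Along chromosome 11, the medians of 5 Mb windows lay below that of all genes throughout, from −0.36 to −0.15 in low against parental and from −0.40 to −0.05 in high against parental. On the X chromosome, 17 of 20 windows lay above that of all genes in high against parental.

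**Figure D4:**
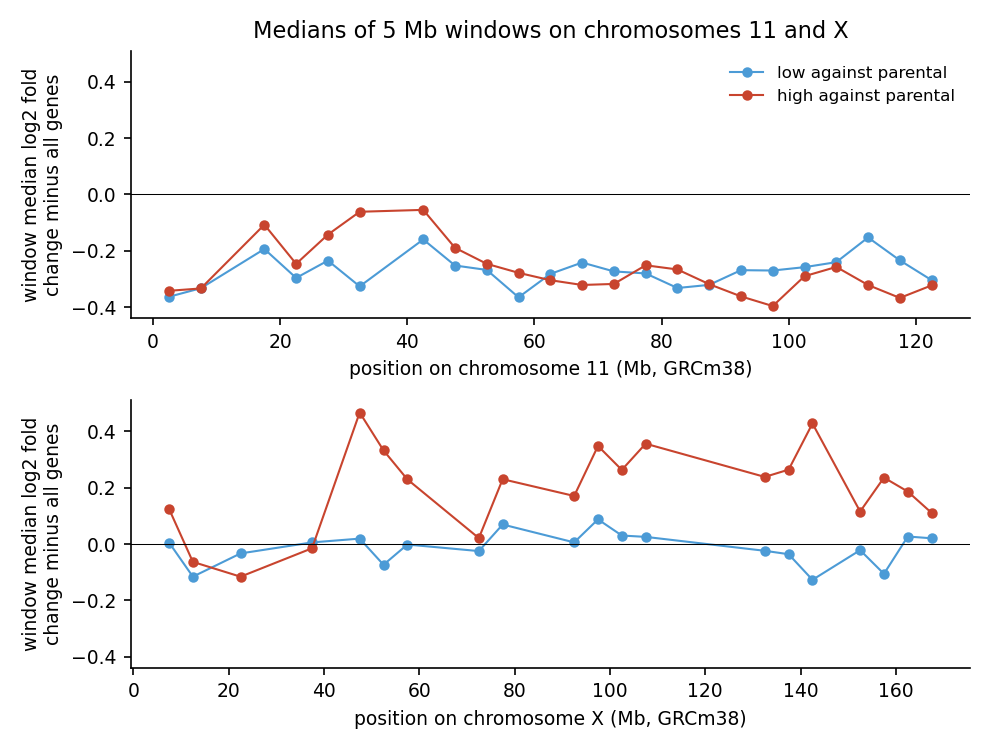
Medians of log2 fold change over 5 Mb windows with at least 10 tested genes, minus that of all genes (vertical), by position in Mb (horizontal), on chromosomes 11 (top) and X (bottom). Blue points are low and red points high against parental. All 23 windows of chromosome 11 lie below 0 for both.

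Fold changes also followed gene length in high cells, by exon length as well as by genomic span. From the shortest to the longest eighth of genes by exon length, the median log2 fold change went from −0.15 to 0.13 in high against parental. From the shortest to the longest eighth of genes by genomic span (0.06 to 2.62 kb and 92.6 to 2960.9 kb), it went from −0.12 to 0.18 in high against parental. It went from −0.03 to 0.06 in low against parental and from −0.09 to 0.09 in high against low.

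**Figure D5:**
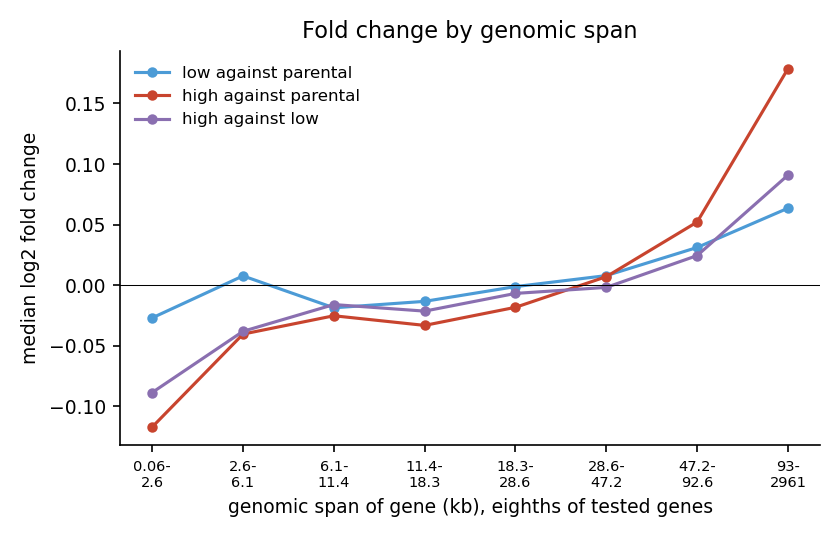
Median log2 fold change (vertical) of tested genes in eighths of genomic span in kb (horizontal), for the 3 comparisons. In high against parental the medians run from −0.12 in the shortest to 0.18 in the longest eighth.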

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

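The 5 Mb window test of the X chromosome was chosen after the result had been seen, as was its split at 40 Mb.

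In 251 genes the derived groups differed in direction: they were called in both against parental and with opposite signs. The direct comparison of high with low called all 251, which follows largely from how they were chosen and is no independent evidence. In high against parental 60 of them changed by 2-fold or more, and each of those 60 rose in high and fell in low cells.

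The X chromosome differed between the derived groups, with a median of 0.15 in high against low relative to all genes. A fit of fold change on expression level, exon length and genomic span left a departure of 0.149 in high against parental, which argues against these measures as the whole cause. A gain of the whole X chromosome in part of the cells is a candidate explanation, and it would raise windows along the whole chromosome. A gain of only a stretch of it would not, and was not tested. Of the 5 Mb windows, 85% (17 of 20) lay above the median of all genes, between the bounds of 75% and 90% set for the test, and the 18 autosomes other than chromosome 11 had 38.5% to 100%, so copy number cannot be told apart from a response of X-linked genes. The 4 windows of the first 40 Mb ran from −0.12 to 0.12, while all 16 beyond 40 Mb were above 0, from 0.02 to 0.47. The 127 genes of the first 40 Mb had a median of −0.0051 relative to all genes (37 rose, 29 fell). The 445 genes beyond it had 0.207 (176 rose, 49 fell).

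Mitochondrially encoded genes differed between the derived groups, with a median of 0.26 in high against low relative to all genes (8 risers and 2 fallers among 28; 4 and 2 among the 13 longer than 250 bases). Leaving out single libraries gave 0.18 to 0.31. Several of the 28 genes had few counts, as given above.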

How the results depend on the processing

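Of 544 values recomputed under alternatives, 535 kept their direction and their side of the threshold, or stayed within 1.5 times for a count, 3 counts moved further, 3 medians lost their call, and 3 medians without a call turned sign. In low against parental, the genes changed by 2-fold or more numbered 111 with DESeq2 in place of 198, the genes changed numbered 1951 at an adjusted p under 0.01 in place of 3134, and 993 in place of 1727 fell without chromosomes 11 and Y, where fewer genes were tested. Without a low-count filter the mitochondrial medians of 0.19 (high against parental, adjusted p = 0.165) and 0.17 (high against low, adjusted p = 0.166) lost their calls, with 36 genes in place of 28. Leaving out parental replicate 1 ended the first of these calls (0.0331), and leaving out single libraries gave 0.03 to 0.47 for it. The Y median in low against parental was −0.33 in place of −0.51 without that filter, with 29 genes in place of 9. The medians that turned sign were Y in high against parental (−0.36 to 0.0324 over single libraries left out) and X in low against parental (−0.0156 to 0.0055). The cause was not tested.

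Leaving out single libraries gave 2290 to 3173 genes changed in low against parental, 6734 to 7666 in high against parental and 4978 to 6440 in high against low. Same-direction calls were 1575 to 2074, and Zmynd8 log2 fold changes 0.45 to 0.47, 1.29 to 1.37 and 0.83 to 0.91. That of ENSMUSG00000022044 in high against parental was 6.86 without parental replicate 1 and 10.14 without parental replicate 3. Across all alternatives the chromosome 11 median stayed between −0.29 and −0.25 in low and between −0.30 and −0.27 in high. Without chromosome 11 genes, a choice made after the data had been seen, 2463, 6874 and 5435 genes changed.

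The replicate numbers showed no clear pairing of the libraries: the correlations of same-numbered deviations from the group means lay between −0.02 and 0.04. In high against low each library correlated best with its own number, at 0.0080 to 0.019, but in the other comparisons not every library did. A weak pairing is not excluded. With replicate number as a block, 3611, 8076 and 6403 genes changed in the comparisons of low with parental, high with parental and high with low. Without the block they numbered 3134, 7708 and 5946. The block ended no call of Zmynd8 or of the chromosome 11, X, Y and mitochondrial medians, the only ones recomputed.

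The gene list tests and their alternatives, among them an estimated correlation between genes, were not run because the files do not pair identifiers with symbols. Changes of 1.2-fold were recovered for 48%, 46% and 24% of simulated genes in low against parental, high against parental and high against low. Far fewer genes changed in these simulations than in the data, so the shares are not the sensitivity of the real calls. Of those below the median count of the changed genes, 2 of 24, 2 of 27 and 0 of 24 were recovered, and of the rest 22 of 26, 21 of 23 and 12 of 26.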

Other observations

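The tests of neighbouring genes and of windows were chosen after the data had been seen, and those of gene length after the trend had been seen, with bounds set before their results. The window test of chromosome 11, the tests of its parental libraries and of the Zmynd8 level, and the counts over other splits were also chosen after the results had been seen.

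Strongly changed genes lay next to each other more often than shuffled genes. Among genes called with a change of at least 2-fold, 173 adjacent pairs changed in the same direction in high against parental, against a mean of 71.4 and a highest of 106 in 10000 shuffles (one-sided permutation p = 0.0001, the smallest possible). The pairs numbered 10 in low against parental (shuffled mean 1.92) and 110 in high against low (shuffled mean 45.4), with the same p.

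Some windows departed in their median from their own chromosome, though not every gene in them changed. Of 555 windows of 3 Mb, 4 were called in low against parental, 9 in high against parental and 19 in high against low (permutation, adjusted p under 0.05). In high against parental, those on chromosomes 2, 5, 10, 11, 13 and 15 lay below their chromosome, and those on 3, 12 and 17 above. High against low had windows both above and below. Only some of the called windows are given here. On chromosome 17, from 21 to 24 Mb, 26 of 51 genes rose and 2 fell in high against parental, with a median of 0.56, and the median was 0.15 in low against parental (9 rose, 1 fell). The 26 genes at 18 to 21 Mb of chromosome 12 had medians of 0.30 in low (4 rose, 0 fell) and 0.44 in high (6 rose, 0 fell) against parental. On chromosome 13, from 21 to 24 Mb, the 60 genes had medians of −0.42 in low (3 rose, 13 fell) and −0.34 in high (9 rose, 12 fell) against parental. The 11 genes at 9 to 12 Mb of chromosome 7 had a median of 0.52 in low against parental (4 rose, 0 fell) and −0.95 in high against low (0 rose, 6 fell). On chromosome 3, from 141 to 144 Mb, where ENSMUSG00000028270 lies, the median of 11 genes was 0.76 in high against parental (7 rose, 1 fell) and 1.46 in high against low (6 rose, 1 fell). Neighbouring genes can be near-identical copies, whose counts are uncertain.

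Among mitochondrially encoded genes, picked here after their values were seen, the gene at 14145 to 15288 of the mitochondrial genome rose from 727 ± 98.3 to 1550 ± 45.7 CPM in high cells (SD, n = 3 each; edgeR log2 fold change 1.09, adjusted p = 1.6e-05). The gene at 70 to 1024 fell from 282 ± 30.5 to 195 ± 15.7 (SD, n = 3 each; log2 fold change −0.54, edgeR adjusted p = 2.7e-05). Whether these genes make mRNAs or other RNAs was not determined here.

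Chromosome 11 genes were lower in both derived groups by similar amounts. Expression level, exon length and span do not account for it, since −0.25 was left after a fit on them in the comparison that kept less, nor does a deviating parental library, since the lowest parental share of counts lay 1.84 percentage points above the highest other. A response that grows with the Zmynd8 level is argued against by a median of −0.0143 in high against low. A lower copy number of chromosome 11 in both derived lines, or a gain in the parental cells, is a hypothesis that the window test could not decide. All of its 5 Mb windows (100%, 23 of 23) lay below the median of all genes in both comparisons, against 0% to 38.5% of windows on the 18 other autosomes. With 86.1% (low) and 79.2% (high) of its genes below that median, this was nearly bound to follow. It shows that the shift ran along the chromosome, which a response of its genes could also give. A difference of 3 against 2 copies in every cell would give −0.58; for a gain in parental cells only, with expression in proportion to copies, the extra copy would be needed in 42.1% or 45.3% of them, while shares for a loss in the derived lines were not computed, and a response of chromosome 11 genes that is already complete at the low level stays open.

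Long genes were higher in high cells, with medians by genomic span from −0.12 in the shortest eighth to 0.18 in the longest eighth in high against parental, and by exon length from −0.15 to 0.13. Leaving out chromosomes 11, X, Y and MT removed 0.765% of the difference, so these do not account for it. Counting that depends on exon length may contribute: within bins of similar exon length the mean Spearman correlation of span and fold change was 0.0518, against 0.178 over all genes, and it lay between the bounds of 0.03 and 0.1, while exon length kept 0.121 within bins of similar span. Variation in length bias between libraries also cannot be told apart, since the difference between group means was 1.91 times the largest range within a group. This lay between the bounds set for it. Centred on the mean of all libraries, the long minus short median was 0.0995 to 0.158 in high libraries. It was −0.0983 to 0.0007 in low and −0.182 to −0.0413 in parental libraries, so high libraries did not overlap the others. A response of long genes to the Zmynd8 level was not tested apart from exon length dependent counting and variation between libraries.

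With 3 libraries against 3 there are 10 splits, so a share under 0.05 cannot be reached. The real split called 3134, 7708 and 5946 genes in low against parental, high against parental and high against low, and was the 1 split with as many in each. The highest of the others was 0 by edgeR in each comparison, with at most 839, 712 and 383 genes at an unadjusted p under 0.05. Each other split mixes libraries of both groups on either side, so any difference between the groups adds to the spread. Few calls were bound to follow, and these splits are no reference for unchanged groups.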
